A study of Vitis x labruscana x Vitis vinifera with 36 samples.

How the data were processed

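Gene expression was measured by RNA sequencing in berry flesh and berry skin of the table grape 'Shine Muscat', a hybrid of Vitis labruscana and Vitis vinifera. The labels distinguish seedless from seeded berries and give 3 sampling stages, numbered 1, 3 and 4, so that the 36 libraries form 12 groups of 3. The series title calls the seedless berries treated and the others not treated; the agent, its dose and the calendar of the stages are not given in the sources used here, and stage 2 is not analysed here. Per the labels' protocols, total RNA was taken from skin and flesh separately, purified with a kit and made into libraries with the Lasy-seq method, which indexes transcripts at reverse transcription and reads mainly their 3′ ends.

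One table was used, which holds the raw read counts that the authors deposited, as whole numbers per gene and library with no normalization. Per the submitters' processing notes, reads were trimmed with fastp 0.20.0, aligned with HISAT2 2.2.1 and counted with featureCounts. The genome build, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of near-identical or overlapping genes can therefore be split between copies, and this could not be assessed gene by gene. The table has 30661 rows, of which 29971 carry VIT identifiers and 690 carry ENSRNA identifiers; 7662 rows had no count in any library. It holds 0 summary rows, and 0 of its per-sample columns lay outside the 36 samples. ENSRNA rows took at most 3.14% of a library and were kept. The columns were tied to samples by the treatment, stage, tissue and number in their names.

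The table does not pair identifiers with gene names, and no annotation was used. The 27 lists of gene products fixed before the data were examined (terpenoid, lipoxygenase, carotenoid, flavonoid, hormone, cell wall, seed, lignin, cuticle and others) could therefore not be matched to identifiers and have no result, and neither do the list tests planned on them. Genes are given by identifier, and no function is stated for them.

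Depth ran from 0.61 M to 7.34 M counts per library (M, mega). The seeded stage 1 groups had the lowest mean depth, with 0.61 to 1.25 M per library in flesh and 1.12 to 2.38 M in skin. Low genes are therefore measured least precisely there. The shallowest seeded skin library of stage 4 had 2.23 M. Counts are reads, not independent molecules, so the intervals from counts given below cover counting error only. Every pair of libraries of a group differed by more than counting noise, with at least 3.44 times the variance expected from counting alone over genes with 40 or more reads in the pair, so all 36 were treated as separate samples. The labels do not say whether replicates came from separate vines or berries, so p-values measure the spread between these samples, which may be technical.

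Differential expression was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the groups with a minimum count of 10, TMM scaling, robust dispersion estimates and the robust quasi-likelihood F-test, with Benjamini-Hochberg adjustment over all genes of a contrast and a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. Flesh and skin were fitted separately, each with its 18 libraries and 6 groups, because skin and flesh of one number might come from the same berries. These fits gave the seedless-minus-seeded contrast at each stage, the change of that contrast from stage 1 to stage 4, and the ripening changes averaged over the treatments. Skin was compared with flesh, and the treatment effects of the tissues with each other, in a fit of all 36 libraries. CPM values printed are scaled by TMM.

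The size of the treatment difference was also estimated as a root mean square (RMS) log2 difference over genes with a mean of at least 10 CPM. It uses products of differences between non-overlapping library pairs on log2(CPM + 1), which cancels independent noise, and its standard error is a jackknife over replicates. Overlaps of called genes between contrasts that share no library were compared with the number from independent lists. They were tested with one-sided Fisher's exact tests across genes, which are not independent replicates, with Benjamini-Hochberg adjustment over the 44 tests made. Independent lists treat every tested gene as equally likely to be called, which was not examined. The limit that a count of 0 allows was taken as 3 counts over the reads of a group.

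Genes named in the text follow a rule: a gene passed the adjusted threshold, had a mean of at least 5 CPM, and for the seedless-against-seeded, ripening and tissue contrasts its libraries did not overlap between the sides compared. The 2 largest rises and the 2 largest falls are named for each seedless-against-seeded contrast, and 1 each way for the other contrasts. The part of the rule that needs product names could not be applied.

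The fit was tested on simulated data with the real library sizes, mean levels and dispersions, and 200 genes changed in the seedless arm. For the flesh stage 1 contrast, with 13267 simulated genes, it recovered 44% of 2-fold, 86% of 4-fold and 90% of 8-fold changes, and 5.5% of its calls were false. For flesh stage 4, with 13229 genes, the shares were 52%, 90% and 98%, with 7% false calls. For the stage 4 against stage 1 difference in skin, with 13892 genes, it recovered 34% of 2-fold and 76% of 4-fold changes, with 9.1% false calls. Added after seeing the data, 100 simulated sets gave each gene one effect at stages 1 and 4, with noise of its own standard errors, and took as many genes with the largest change as the real test called.

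Alternatives listed before the data were examined were RLE scaling, no filter on low counts, a minimum count of 30, DESeq2 1.42.0, the replicate number as a block, thinning of all libraries of a fit to its smallest total, leaving out replicates in turn, other sets of libraries in the fit, and for the RMS a minimum of 50 CPM or a pseudocount of 5 CPM. Thinning for the RMS and the ripening change within each treatment were added after seeing the data. The volatile profiles named in the series design, and a co-expression network built on them, were not analysed here.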

Results

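Transcript levels were compared between seedless and seeded 'Shine Muscat' berries in flesh and in skin at stages 1, 3 and 4, with 3 libraries in each of the 12 groups. Mean depth was 3.81 ± 0.23 M counts (SD, n = 3) in seedless flesh and 0.86 ± 0.35 M in seeded flesh at stage 1. In skin at stage 1 it was 3.61 ± 0.57 M in seedless and 1.82 ± 0.64 M in seeded berries. At stages 3 and 4 the group means lay between 3.47 M (seeded flesh, stage 3) and 6.35 M (seedless flesh, stage 3). At an equal depth of 608901 counts, seeded flesh at stage 1 held 13530 ± 292 detected genes and seedless flesh 13881 ± 99. Libraries of a group correlated at 0.960 or more on log2 CPM in 10 groups; the seeded stage 1 libraries correlated at 0.868 to 0.893 in flesh and 0.925 to 0.943 in skin. The deposited table does not pair identifiers with names, so genes are given by identifier.

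Tissue and ripening separated the libraries first. The first principal component held 36.6% of the variance and separated skin, with group means from 21.3 to 80.3, from flesh, with group means from -77.7 to -16.8. The second component held 19.7% and followed the stages. In flesh, the seedless group means on it were -28.1 ± 1.0 at stage 1, -10.5 ± 2.7 at stage 3 and 26.7 ± 3.6 at stage 4 (SD, n = 3). The seeded flesh groups lay at -88.5 ± 8.5, -24.9 ± 1.2 and 35.4 ± 6.0 at the same stages. Skin had the same order, from 0.1 ± 3.5 to 52.5 ± 3.7 in seedless and from -47.6 ± 3.8 to 59.2 ± 5.0 in seeded berries. Seeded berries lay below seedless berries at stages 1 and 3 and above them in the mean at stage 4, in both tissues. The seeded stage 1 groups also had the lowest mean depth, and the components were not computed at one depth.

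**Figure D1:**
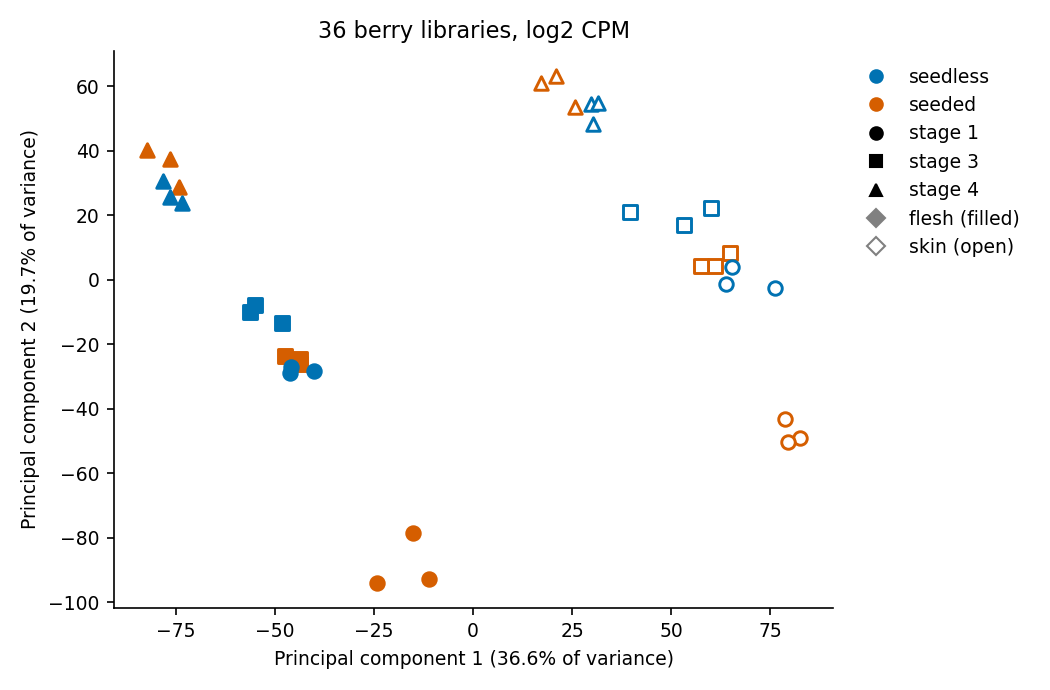
Principal components 1 and 2 of log2 CPM (prior count 2) for the 36 libraries, 1 point per library; colour gives the treatment, shape the stage and fill the tissue. Skin and flesh separate along component 1 (36.6% of variance), and the seeded stage 1 libraries lie lowest along component 2 (19.7%) within their tissue.

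The first comparison asked how seedless and seeded berries differed at each stage. In flesh at stage 1, 2339 of 13639 tested genes differed: 1200 were higher and 1139 lower in seedless berries, and 538 of the former and 524 of the latter by at least 2-fold. VIT_14s0108g00800 had 13 ± 2.13 CPM in seedless and 0.598 ± 1.04 CPM in seeded flesh (SD, n = 3; edgeR adjusted p = 4.9e-06). Only 1 read lay behind the seeded value, and the ratio of pooled reads was 31.7 (95% exact Poisson interval 5.6 to 1260). VIT_19s0015g00860 was also higher, at 12.2 ± 3.03 against 0.971 ± 1.68 CPM, with 2 seeded reads and a ratio of 14.8 (4.03 to 124; edgeR adjusted p = 9.4e-05). VIT_14s0060g00990 fell by 3.96 ± 0.75 log2 units (SE; edgeR adjusted p = 0.00025), from 14.9 ± 10 CPM in seeded to 0.927 ± 0.169 CPM in seedless flesh. VIT_00s0189g00010 fell by 3.79 ± 0.85 (edgeR adjusted p = 0.0015), from 11.2 ± 5.91 to 0.727 ± 0.534 CPM. The seeded libraries of this comparison were the shallowest flesh libraries and spread most. ENSRNA rows took 0.924% to 3.14% of them against 0.552% to 0.696% of the seedless ones. Thinned to one depth, the test called 1388 genes.

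In flesh at stage 3, 1460 genes differed, 702 higher and 758 lower in seedless berries. Among genes that met the naming rule, the largest rises were in genes with neighbouring numbers. These were VIT_13s0019g02770 (3.25 ± 0.51 log2 units, SE, edgeR adjusted p = 0.00057) and VIT_13s0019g02760 (3.16 ± 0.46, edgeR adjusted p = 1.1e-05). Whether these share reads could not be assessed. VIT_13s0019g02770 had 43.8 ± 13.3 CPM in seedless and 4.52 ± 2.55 CPM in seeded flesh, and at stage 1 was lower in seedless flesh (-1.93 ± 0.50; edgeR adjusted p = 0.015). VIT_14s0219g00130 fell by 3.07 ± 0.47 (edgeR adjusted p = 1.5e-05). VIT_01s0137g00240 fell by 2.61 ± 0.27 (edgeR adjusted p = 9.4e-08), from 53.7 ± 6.33 to 8.53 ± 4.06 CPM. This gene was lower in seedless flesh at stage 1 (-1.57 ± 0.26) and stage 4 (-1.79 ± 0.46) as well, with edgeR adjusted p = 9.7e-05 and 0.023. Without seedless flesh replicate 1 or seeded flesh replicate 1 of this stage, 964 and 972 genes were called, and at one depth 555.

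In flesh at stage 4, 505 genes differed, 321 higher and 184 lower. VIT_08s0007g04180 was 18.3-fold higher in seedless flesh (4.20 ± 0.34 log2 units, SE; edgeR adjusted p = 3.4e-09), at 49.8 ± 14.1 against 2.73 ± 0.566 CPM; at stages 1 and 3 its difference was -0.52 ± 0.31 and 0.22 ± 0.24. VIT_12s0057g00120 had 94.9 ± 60 CPM in seedless and 5.3 ± 1.38 CPM in seeded flesh (edgeR adjusted p = 0.016). Its call was lost without seedless flesh replicate 1 or 2 (edgeR adjusted p = 0.052 and 0.058) or seeded flesh replicate 1 or 3 (0.074 and 0.083), and its adjusted p ranged from 5.9e-07 with DESeq2 to 0.11 with edgeR on the 6 libraries alone. VIT_11s0016g03180 fell by 2.01 ± 0.21 (edgeR adjusted p = 1.2e-08) and VIT_04s0079g00410 by 1.77 ± 0.17 (edgeR adjusted p = 2.3e-09). Both had been higher in seedless flesh at stage 3, by 0.75 ± 0.23 and 0.84 ± 0.19 (edgeR adjusted p = 0.032 and 0.0022). At stage 1 the former was lower (-0.93, edgeR adjusted p = 0.0098) and the latter higher (1.17 ± 0.29, edgeR adjusted p = 0.0039). Without seedless flesh replicate 1, seedless flesh replicate 2 or seeded flesh replicate 3 of this stage the test called 301, 242 or 257 genes, and at one depth 180.

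In skin at stage 1, 2872 of 14193 tested genes differed, 1471 higher and 1401 lower in seedless skin, of which 548 and 541 by at least 2-fold. VIT_11s0016g04160 was 29.1-fold higher (4.86 ± 0.29 log2 units, SE; edgeR adjusted p = 7.8e-14), at 81.9 ± 4.41 against 2.95 ± 0.907 CPM, and stayed higher by 1.29 ± 0.16 at stage 3 and 0.58 ± 0.15 at stage 4 (edgeR adjusted p = 9.8e-07 and 0.022). VIT_09s0018g01980 rose by 3.88 ± 0.55 (edgeR adjusted p = 1.5e-06). VIT_04s0008g05640 fell by 6.16 ± 0.53 (edgeR adjusted p = 3.4e-10), from 62 ± 35.7 CPM in seeded to 0.825 ± 0.693 CPM in seedless skin. VIT_01s0137g00790 was also lower (edgeR adjusted p = 3.4e-06), with 2 reads in seedless and 70 in seeded skin, a ratio of 69.6 (95% exact Poisson interval 18.6 to 586). The seeded skin libraries of this stage were also the shallower ones, and ENSRNA rows took 0.622% to 1.66% of them against 0.480% to 0.619%.

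In skin at stage 3, 1507 genes differed, 730 higher and 777 lower. Among genes that met the naming rule, VIT_13s0019g02760 again had a large rise (4.62 ± 0.47 log2 units, SE, edgeR adjusted p = 2.1e-05). It had 103 ± 22.4 against 4.1 ± 2.96 CPM. VIT_03s0091g00230 followed (4.30 ± 0.49, edgeR adjusted p = 2.2e-07), and at stage 4 was lower in seedless skin (-2.72 ± 0.55, edgeR adjusted p = 0.0027). VIT_01s0011g02720 fell by 3.73 ± 0.58 (edgeR adjusted p = 0.00016) and VIT_08s0007g07480 by 3.27 ± 0.46 (edgeR adjusted p = 2.5e-06). Without seedless skin replicate 3 of this stage 997 genes were called, and at one depth 890.

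In skin at stage 4, 494 genes differed, 293 higher and 201 lower. VIT_12s0057g00090 and VIT_12s0057g00150, whose identifiers share their stem with VIT_12s0057g00120, rose by 3.33 ± 0.58 and 2.84 ± 0.48 log2 units (SE; edgeR adjusted p = 0.0059 and 0.00029). VIT_08s0007g00330 fell by 3.27 ± 0.63 (edgeR adjusted p = 0.012), from 228 ± 32 to 24 ± 23 CPM. VIT_07s0104g01340 fell by 2.56 ± 0.58 (edgeR adjusted p = 0.006), and in flesh at stage 3 was higher in seedless berries (1.82 ± 0.42; edgeR adjusted p = 0.0052). The call of VIT_08s0007g00330 was lost without seedless skin replicate 1 or 2 (edgeR adjusted p = 0.07 and 0.052; range over alternatives, DESeq2 included, 0.00023 to 0.093). That of VIT_07s0104g01340 was lost without seeded skin replicate 3 (edgeR adjusted p = 0.055; range over alternatives 5.9e-05 to 0.055). Without seedless skin replicate 1, seedless skin replicate 2 or seeded skin replicate 3 the test called 289, 280 or 253 genes. At one depth 312 genes were called, and a fit of only the 6 libraries called 785.

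**Figure D2:**
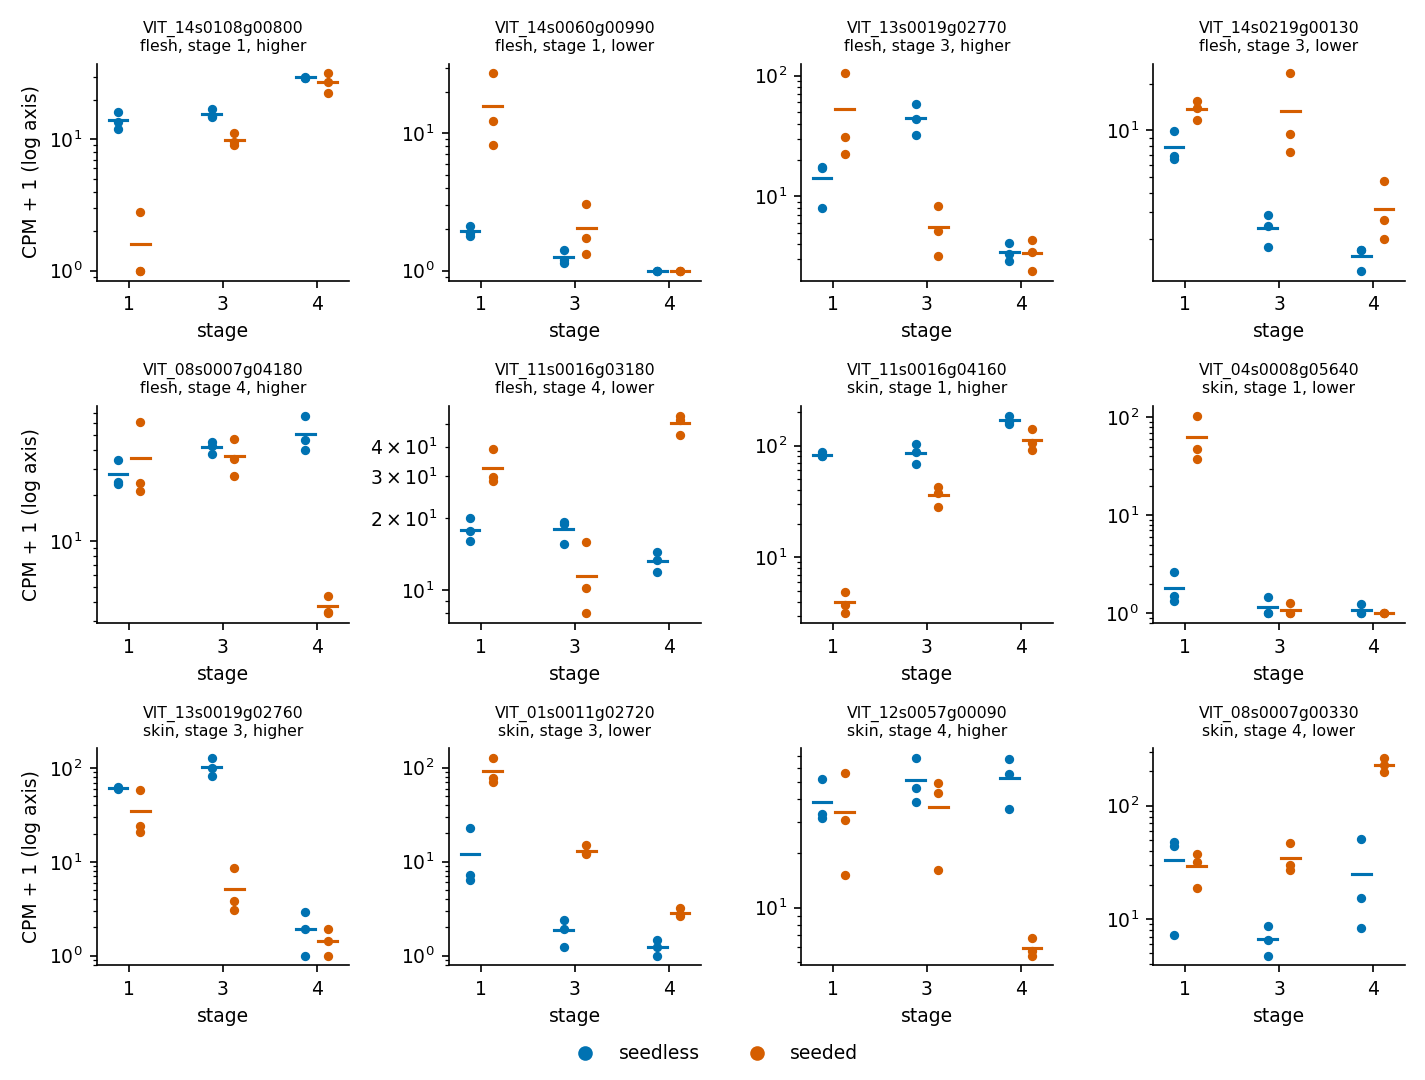
CPM + 1 on a log axis at stages 1, 3 and 4 for the gene with the largest rise and the largest fall in each seedless-against-seeded contrast. Only genes that met the naming rule were ranked, with a mean of at least 5 CPM and no overlap between treatments. Points are libraries (n = 3 per treatment and stage) of the tissue named above each panel, and bars are means. VIT_08s0007g04180 reached 49.8 against 2.73 CPM in flesh at stage 4, and VIT_11s0016g04160 reached 81.9 against 2.95 CPM in skin at stage 1.

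Genes called in both tissues mostly changed in the same direction. Of 13228 genes tested in both, 512 were called higher and 595 lower in seedless berries in both tissues at stage 1, against 127 and 109.7 for independent lists; 26 were called in opposite directions against 236.2. At stage 3, 288 were higher and 298 lower in both, against 35.9 and 41.4, and 7 were opposite against 77.1. At stage 4, 88 were higher and 52 lower in both, against 6.5 and 2.6, and 0 were opposite, where independent lists give 8.3. Over the 6 same-direction overlaps the highest p of Fisher's exact test across genes was 2.5e-54 (adjusted over 44 such tests, 8.5e-54). The correlation of log2 fold changes across all these genes was 0.41, 0.48 and 0.36 at stages 1, 3 and 4; genes are not independent replicates. The labels do not say whether skin and flesh came from the same berries, and the seeded stage 1 libraries of both tissues were the shallow ones.

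**Figure D3:**
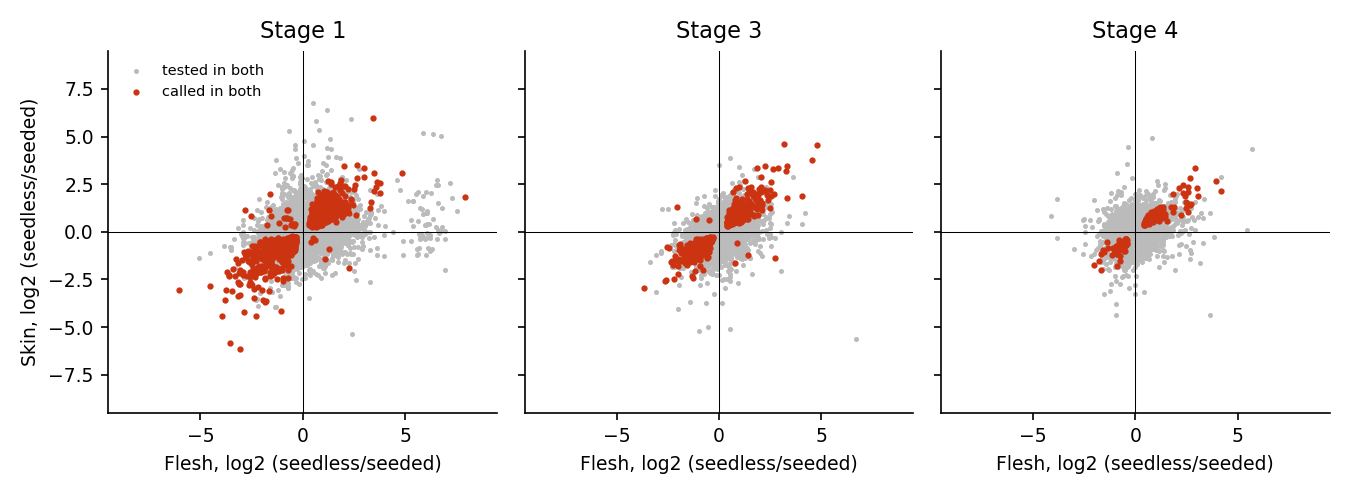
Log2 (seedless/seeded) in flesh (x axis) and skin (y axis) for the 13228 genes tested in both tissues, at each stage; red points passed an adjusted p of 0.05 in both tissues. The red points lie almost wholly in the quadrants of equal sign, with 26 of 1133 opposite at stage 1, 7 of 593 at stage 3 and 0 of 140 at stage 4; the 69 points beyond 4 on the x axis at stage 1 are genes with at most 1 read in seeded flesh, whose fitted fold depends on the prior count.

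The series title speaks of aroma profiles that grow more alike as berries ripen. Aroma was not analysed here; for transcripts, the stage counts alone do not test such a change. The difference between seedless and seeded berries at stage 4 was itself not equal to that at stage 1 for 1665 genes in flesh and 2180 in skin. The stage 4 difference was the smaller one in size for 1410 of these genes in flesh (84.7%) and 1762 in skin (80.8%). Choosing genes by their change favours a larger value in the noisier stage 1 groups: in simulated data with equal effects at both stages the share averaged 62.5% in flesh and 55.4% in skin. At one depth the observed share was 80% in flesh and 80.2% in skin, while the simulation used the standard errors at full depth. Effects that change from gene to gene but keep their overall size were not simulated. VIT_04s0008g01570 was lower in seedless than in seeded flesh at stage 1, at 4.72 ± 1.57 against 34.4 ± 9.07 CPM (SD, n = 3), and at stage 4 had 1.28 ± 0.409 against 0.157 ± 0.273 CPM, the latter from 2 reads (edgeR adjusted p = 2.5e-05 for the change). VIT_07s0104g01340 was the opposite in flesh, with 2.84 ± 1.35 CPM against 0 reads at stage 1, which allow up to 1.17 CPM, and 23.9 ± 1.75 against 46.6 ± 6.82 CPM at stage 4 (edgeR adjusted p = 0.033, and 0.24 without replicate 1). In skin, VIT_12s0028g01370 went from 4.20 ± 0.962 against 9.47 ± 3.00 CPM to 8.26 ± 1.82 against 0.148 ± 0.256 CPM, the latter from 1 read (edgeR adjusted p = 4.4e-07). VIT_03s0091g00230 went from 16.0 ± 0.888 against 2.05 ± 2.66 CPM to 0.945 ± 0.233 against 6.65 ± 2.14 CPM (edgeR adjusted p = 6.9e-06). Leaving out replicate 1, 2 or 3 from every group gave 1026, 1056 and 749 genes in flesh, and leaving out replicate 3 gave 1182 in skin. At one depth the counts were 734 and 1381, with the calls of VIT_04s0008g01570 and VIT_07s0104g01340 lost (edgeR adjusted p = 1 and 0.055; lowest over alternatives 4.4e-08 and 0.00064).

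The RMS difference, which does not depend on how many genes a test can call, fell over the stages in both tissues. In flesh it was 0.523 ± 0.026 log2 units at stage 1, 0.367 ± 0.037 at stage 3 and 0.287 ± 0.033 at stage 4 (jackknife SE, n = 3 per arm, 8998 genes). In skin it was 0.495 ± 0.028, 0.367 ± 0.014 and 0.259 ± 0.023 (9349 genes). Values with one library left out did not overlap between stages, at 0.497 to 0.538, 0.345 to 0.400 and 0.265 to 0.312 in flesh and 0.479 to 0.515, 0.356 to 0.377 and 0.241 to 0.271 in skin; no test across stages was made. With all libraries at one depth the estimates were 0.516, 0.376 and 0.304 in flesh and 0.496, 0.371 and 0.263 in skin.

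**Figure D4:**
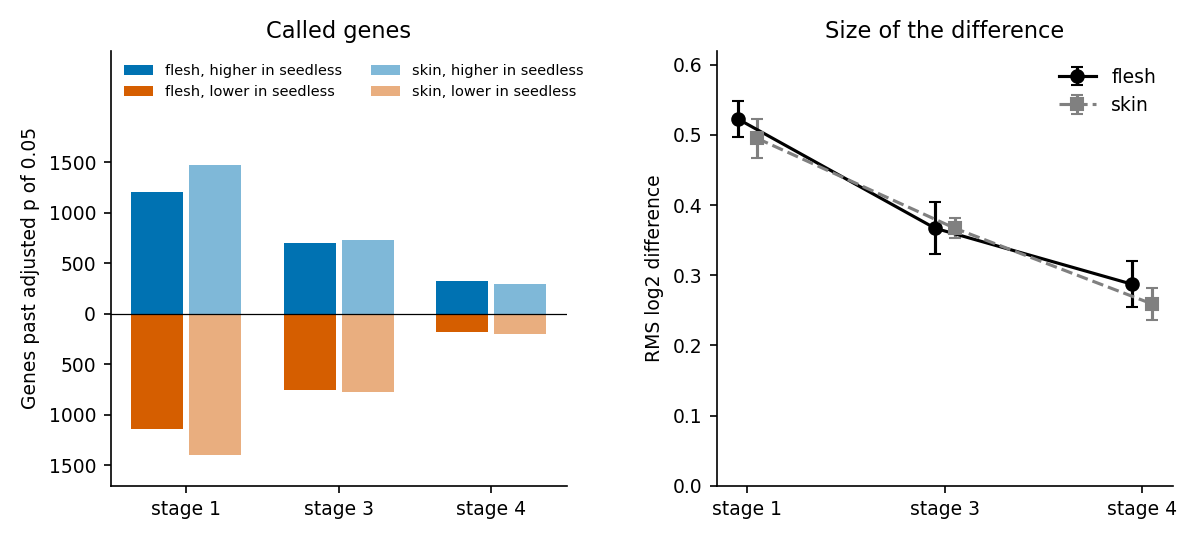
Left, numbers of genes past an adjusted p of 0.05 that were higher (above 0) or lower (below 0) in seedless berries, by stage and tissue. Right, RMS log2 difference between seedless and seeded berries with jackknife SE (n = 3 per arm); it falls from 0.523 to 0.287 in flesh and from 0.495 to 0.259 in skin.

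Overlaps between stages were counted within each tissue. In flesh, 187 genes were higher and 208 lower in seedless berries at both stage 1 and stage 3, against 61.8 and 63.3 for independent lists. In skin these numbers were 299 and 328 against 75.7 and 76.7, and over these 4 overlaps the highest p of Fisher's exact test across genes was 1e-46 (adjusted, 2.9e-46). Between stage 1 and stage 4, more genes changed sides in skin than kept their direction. In skin 76 were higher and then lower and 77 lower and then higher, together 153 against 49.8 expected (Fisher's exact test across genes, p = 3e-25 and 3.8e-16; adjusted, 7.8e-25 and 8.4e-16). In skin 40 stayed higher and 31 stayed lower against 30.4 and 19.8 (exact p = 0.042 and 0.0081; adjusted, 0.066 and 0.013), so the excess that stayed higher did not pass the adjustment. In flesh 32 went from higher to lower and 44 from lower to higher, together 76 against 43 (exact p = 0.00014 and 0.00073; adjusted, 0.00025 and 0.0012). In flesh 50 stayed higher and 39 stayed lower against 28.2 and 15.4 (exact p = 4.8e-05 and 4.4e-08, adjusted 8.8e-05 and 8.8e-08). Both kinds of overlap were thus above independent lists in flesh, so these p-values do not show that directions were kept or changed. Over all 13639 genes the stage 1 and stage 4 differences in flesh correlated at 0. Of the genes called at stage 1 in flesh, 46.1% had the same sign at stage 4. Between stage 3 and stage 4, in flesh 99 stayed higher and 59 stayed lower against 16.5 and 10.2 (exact p = 7.6e-51 and 1.3e-29; adjusted, 2.4e-50 and 3.6e-29), and 28 changed sides against 27.3. In skin 34 stayed higher and 33 stayed lower against 15.1 and 11 (exact p = 7.7e-06 and 1.3e-08; adjusted, 1.5e-05 and 2.7e-08). In skin 46 went from higher to lower and 60 from lower to higher, together 106 against 26.4 (exact p = 4.2e-18 and 2.5e-19; adjusted, 9.7e-18 and 6.1e-19). At stage 4 the median difference, in the direction called at stage 1, was -0.03 log2 units for the genes called at stage 1 in flesh and -0.06 for those in skin.

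Ripening was followed as the change between stages. From stage 1 to stage 3, averaged over treatments, 1147 genes rose and 1166 fell in flesh, and 1433 rose and 1594 fell in skin. From stage 3 to stage 4, 2266 rose and 2809 fell in flesh, and 2208 rose and 2649 fell in skin. In flesh, VIT_07s0130g00200 rose by 3.25 ± 0.27 log2 units (SE; edgeR adjusted p = 4.7e-11) and VIT_04s0008g05640 fell by 4.31 ± 0.46 (edgeR adjusted p = 1.3e-08) between stages 1 and 3. VIT_02s0025g02600 rose by 3.70 ± 0.40 (edgeR adjusted p = 2.3e-07) and VIT_13s0019g02850 fell by 4.34 ± 0.23 (edgeR adjusted p = 9.1e-10) between stages 3 and 4. In skin, VIT_05s0077g01150 rose by 3.12 ± 0.13 (edgeR adjusted p = 1.3e-12) and VIT_03s0063g02360 fell by 4.35 ± 0.15 (edgeR adjusted p = 4.3e-14) between stages 1 and 3. VIT_03s0063g01330 rose by 5.47 ± 0.46 (edgeR adjusted p = 1.4e-10) and VIT_13s0019g02820 fell by 5.50 ± 0.44 (edgeR adjusted p = 2.7e-07) between stages 3 and 4. From stage 3 to 4, 1342 genes rose and 1781 fell in both tissues, against 352 and 519.8 for independent lists, and 50 went in opposite directions against 856.1. The stage 1 to 3 count in flesh was 1477 without replicate 2 and 1195 without replicate 3, and in skin 1815 and 1930; the stage 3 to 4 count in skin was 3157 without replicate 2. At one depth the 4 counts were 1189 and 2495 in flesh and 1883 and 3172 in skin. The seedless libraries alone gave 789 and 1982 in flesh and 871 and 1892 in skin, and the seeded libraries alone, equal in number, gave 2413 and 4317 in flesh and 3078 and 4434 in skin.

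Skin and flesh differed in 8281 of 14841 tested genes, 4411 higher and 3870 lower in skin. By at least 2-fold, 1891 were higher and 673 lower in skin. VIT_09s0002g03640 had 16.3 ± 5.66 CPM in skin and 0.199 ± 0.386 CPM in flesh (SD over 18 libraries each; edgeR adjusted p = 1.9e-27). VIT_05s0020g03970 was 16.6-fold lower in skin (-4.05 ± 0.14 log2 units, SE; edgeR adjusted p = 2.7e-27), at 3.19 ± 1.78 against 60.1 ± 36.1 CPM. At one depth, where 9970 genes were tested, 4766 were called.

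A test of whether the treatment effect itself differed between skin and flesh, averaged over stages, called 361 genes, 214 with the higher and 147 with the lower seedless-minus-seeded difference in skin. VIT_14s0066g00400 (edgeR adjusted p = 0.017 over stages) was higher in seedless skin at stage 1, at 13.5 ± 1.29 against 1.15 ± 0.2 CPM (SD, n = 3). In flesh at stage 1 it had 0.361 ± 0.419 against 2.26 ± 2.76 CPM, from 4 reads in each treatment. It was not tested in the flesh fit, so no difference in flesh is read from these values. VIT_04s0008g02510 had 12 ± 7.5 against 14.3 ± 6.14 CPM in skin and, in flesh at stage 1, 1.64 ± 0.247 CPM against 0 reads, which allow up to 1.17 CPM (edgeR adjusted p = 0.04 over stages). Both calls were lost without replicate 1, 2 or 3 (edgeR adjusted p = 0.057 to 0.46 and 0.093 to 0.45; lowest over alternatives 0.00061 with DESeq2 and 0.015). The count fell to 166, 91 and 73. It was 59 at one depth, 553 without a filter on low counts and 547 with DESeq2.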

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

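In this part the counts of other splits, the simulation with no change and the RMS at one depth were chosen after the results were seen. The depth test on counts of called genes and the position and ripening tests were set up before their values were known. They were set up after the principal components had been seen.

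The first pattern is that the difference between seedless and seeded berries was not the same at stage 4 as at stage 1, for 1665 genes in flesh and 2180 in skin, a difference between groups found by the test of the change itself; it was the smaller at stage 4 for 84.7% and 80.8% of these genes (62.5% and 55.4% in data simulated with no change), and the seeded stage 1 libraries were shallow. Unequal depth is argued against as the whole cause. With every library thinned to one total the test of the change still called 734 genes in flesh and 1381 in skin. The RMS difference at stages 1 and 4 was then 0.516 and 0.304 in flesh and 0.496 and 0.263 in skin. Stage 1 counts at one depth were 7.71 times those of stage 4 in flesh and 6.49 times in skin. Low depth tends to lower stage 1 counts, so this ratio adds little against depth. A lower quality of the seeded stage 1 libraries stays open: along the treatment axis of the other tissue these 3 libraries ranged over 0.25 of the seedless-seeded gap in flesh and 0.29 in skin, between the limits set for deciding. The shallowest library was not the farthest from the seedless ones in either tissue, but the one with the highest ENSRNA share was, replicate 1 in both (3.14% at position 1.124 in flesh and 1.66% at 1.179 in skin, where 1 is the seeded mean), and a quality shift common to all 6 seeded stage 1 libraries cannot be told apart from the treatment, because no deeper seeded stage 1 library was compared. Of 40 relabellings within stages, 1, the real one, called as many genes in either tissue. The highest others called 1023 and 1645, and the one in skin kept both stages whole with the treatments of one exchanged. Such relabellings stand for no treatment effect at either stage, not for an equal effect at both. They therefore do not decide whether the change of the effect arose by chance.

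The second pattern, again a difference between groups, is the test of the treatment effect in skin against flesh, which called 361 genes. Here 3 of 30 relabellings, the real one included, called as many, and the highest other called 912. Relabellings of this kind stand for no treatment effect in either tissue, not for an equal effect in both. This count therefore does not decide whether the difference between the tissues arose by chance. The relabelling with 912 kept 2 of the 6 stage and tissue sets whole; what raised its count was not tested. No biological explanation was tested for this pattern.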

How the results depend on the processing

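All 40 results for named genes kept their direction in 485 alternative settings, of which 20 lost the call, in 7 of these results. Settings in which a named gene was not tested or had no adjusted p are not among the 485. Of 164 alternative counts of called genes, 123 lay within 1.5 times the main count. RLE scaling moved the median of all genes by at most 0.042 log2 units and the share of higher calls by at most 5.9 percentage points. Thinning to the smallest library called 1388, 555 and 180 genes for the treatment in flesh at stages 1, 3 and 4, and 890 and 312 in skin at stages 3 and 4 (2026 at stage 1). It gave 734 and 1381 for stage 4 against stage 1, 1189 and 2495 for ripening in flesh, 1883 and 3172 in skin, 4766 for skin against flesh and 59 for the treatment effect in skin against flesh; fewer reads and fewer tested genes lower these counts by construction. The last result also gave 553 without a filter and 547 with DESeq2, and a fit of only the 6 libraries gave 785 for skin at stage 4; the cause was not tested. The seedless libraries alone gave 789 and 1982 genes for ripening in flesh (stages 1 to 3 and 3 to 4) and 871 and 1892 in skin, where the seeded alone gave 2413, 4317, 3078 and 4434. A pseudocount of 5 CPM lowered the RMS to 0.440, 0.322 and 0.245 in flesh and 0.426, 0.318 and 0.221 in skin, as it shrinks low genes, and a minimum of 50 CPM gave 0.482 in flesh at stage 1.

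With 1 library left out, the treatment counts ranged from 1817 to 2175, 964 to 1500 and 242 to 398 in flesh at stages 1, 3 and 4, and from 2166 to 2685, 997 to 1250 and 253 to 445 in skin. With a replicate number left out, stage 4 against stage 1 gave 749 to 1056 and 1182 to 1461, ripening in flesh 1195 to 1564 and 3424 to 4381, in skin 1815 to 2176 and 3157 to 4164, skin against flesh 7037 to 7380, and the treatment effect in skin against flesh 73 to 166. RMS values ranged over 0.497 to 0.538, 0.345 to 0.400 and 0.265 to 0.312 in flesh and 0.479 to 0.515, 0.356 to 0.377 and 0.241 to 0.271 in skin.

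The replicate numbers did not meet the rule for paired samples: of 18 seedless-seeded pairs with one number, 0 correlated above 0.1 in their deviations (-0.052 to 0.095), and of 18 flesh-skin pairs 2 did (0.016 to 0.119). All 36 libraries nevertheless correlated best with their own number in the other tissue, a hint from the data and not the design. With the replicate block the treatment counts were 2339, 1508 and 535 in flesh and 2938, 1618 and 595 in skin. Those for stage 4 against stage 1 were 1685 and 2230, and for ripening 2311 and 5062 in flesh and 3101 and 4916 in skin. For skin against flesh the count was 8321, and for the treatment effect in skin against flesh 418. The block moved no count by 1.5 times. It uses the replicate number alone, shared by all groups of a fit. A block for skin and flesh of one treatment, stage and number was not fitted, so these counts do not cover that pairing. The planned list tests were not run, because identifiers could not be tied to products. Small changes were often missed in the simulated data at these depths. There 44% and 60% of 2-fold changes were recovered at stage 1 in flesh and skin, 52% and 62% at stage 4, and 32% and 34% for stage 4 against stage 1. The simulated sets changed 200 genes, where the real contrasts called 494 or more, so recovery in the real contrasts may differ.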

Other observations

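In this part the counts of other splits and the joint relabelling of flesh and skin were chosen after the results were seen; the tests on neighbouring genes and on ripening were set up before their values were known, the latter after the principal components had been seen.

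Genes with consecutive identifier numbers were called in the same direction more often than random placement of the calls gave. Random placement treats every tested gene as equally likely to be called, which was not examined. In flesh at stages 1, 3 and 4, 152, 74 and 20 such pairs were both called higher or both lower in seedless berries, where random placement gave means of 114.5, 44.8 and 5.7 (permutation p = 0.001 each, the smallest that 1000 placements can give; adjusted over the 6 tests, 0.0012). In skin the numbers were 242, 86 and 13 against 168.6, 46.7 and 5.3 (permutation p = 0.001, 0.001 and 0.003; adjusted, 0.0012, 0.0012 and 0.003). Pairs called in opposite directions numbered 96, 56 and 10 in flesh against 113.7, 44.5 and 5 at random, and 136, 42 and 1 in skin against 169.3, 46.7 and 4.8, and were not tested. The longest run at stage 4, singled out after its values were seen, was among identifiers that begin with VIT_12s0057, where 7 consecutive tested genes were higher in seedless flesh and 4 in seedless skin. Pairs within these runs are part of the stage 4 numbers above, and the excess without them was not tested. Of the tested genes with this stem, 11 of 82 were higher and 0 lower in flesh at stage 4, by 2.34 to 4.18 log2 units, and 8 of 84 were higher and 0 lower in skin. At stage 1 the same stem had 7 higher and 8 lower in flesh. Shared regulation of neighbours and reads shared between tandem copies may both produce such runs, and the 20 pairs in flesh do not separate them; sequence would be needed.

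The principal components raised the hypothesis that seedless berries were further along in ripening at stage 1. These components come from the same libraries, so the correlations below in part restate them and are not independent evidence. If it held, the seedless-minus-seeded differences at one stage should follow the ripening change between the other stages, which uses other libraries. Across genes, the stage 1 differences correlated with the stage 3 to 4 change at 0.371 in flesh and 0.385 in skin, where other splits of the same libraries reached 0.274 and 0.324 in size (mean 0.378, exact p = 0.005 over 400 relabellings, the smallest they can give; adjusted over 3 tests, 0.015). With flesh and skin relabelled together, as they might share berries, the exact p was 0.1, the smallest that these 20 relabellings can give, so the test does not decide. The mean was 0.344 with all libraries thinned to one depth, which argues against depth as the cause of the correlation. Of the genes that rose from stage 3 to stage 4 in flesh, 423 were called higher and 73 lower in seedless flesh at stage 1; of those that fell, 174 were higher and 643 lower; in skin the numbers were 575 and 79, and 167 and 720. At stage 3 the mean correlation with the stage 1 to 4 change was 0.232, with 0.277 in flesh, where another split reached 0.317, and 0.187 in skin, where another reached 0.252 (exact permutation p = 0.075; adjusted, 0.11), which leaves the question open. At stage 4, with the stage 1 to 3 change, it was -0.042 (exact permutation p = 0.67; adjusted, 0.67), a mean of 0.015 in flesh and -0.099 in skin. With 1 library left out, these ranged from -0.054 to 0.087 and from -0.163 to -0.054. In skin at stage 4, the genes that rose from stage 1 to 3 were called higher in seedless berries 27 times and lower 61 times, and those that fell 92 and 26 times, the reverse of stage 1; in flesh the numbers were 55 and 25, and 47 and 36. A missed p excludes nothing, so an offset at stage 4, in skin towards seeded berries, stays open. A difference in ripening progress may account for part of the stage 1 differences (0.378) and stays open, as do a quality shift common to the seeded stage 1 libraries and other effects of the treatment.

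Within 6 libraries there are 10 splits, too few for a share under 0.05, and for each of the 6 treatment contrasts 1 split, the real one, gave as many genes. In flesh the real counts were 2339, 1460 and 505 and the highest others 0, 1 and 22; in skin they were 2872, 1507 and 494 against 0, 2 and 1. For ripening, 1 of 40 relabellings within treatments, the real one, gave as many, a share under 0.05. The real counts were 2313 and 5075 in flesh and 3027 and 4857 in skin, and the highest others 1207, 1815, 1640 and 2205. For skin against flesh 1 of 30 gave as many, with 8281 against 1, also a share under 0.05. Replicates may be technical, so these shares speak only to chance among these libraries.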
